A study of Xenopus tropicalis with 44 samples.

How the data were processed

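RNA of whole Xenopus tropicalis embryos was sequenced in 44 libraries of 22 groups. Total RNA was extracted with the RNA Isolator reagent and precipitated with isopropanol, and libraries were made with a stranded mRNA kit, per the labels' protocols. The authors deposited a table of raw read counts per gene with gene lengths, in which the counts are whole numbers and not normalized. Reads were processed with fastp, STAR 2.7.0e, featureCounts 2.0.1 and deepTools, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are given, and values of overlapping or antisense genes and of near-identical copies (the ventx, nodal, sia and bix families, histone and ribosomal protein genes) are uncertain to that extent. Gene names are those of the table. Of its 28778 names 26459 are symbols in the RefSeq annotation of the UCB_Xtro_10.0 assembly, which was used here for names alone.

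Each column was matched to a sample by its name, and groups were taken from the titles and characteristics in the labels. Replicates of a group were compared first. Their counts differed by more than sampling noise in every group (chi-square per gene of 1.40 to 33.7, median 3.56), and the log2 values had Pearson correlations of 0.980 to 0.999 across genes, so no library was counted as a copy of another. Libraries held 9266500 to 37174000 counts. A floor of 3 counts corresponds to 0.0706 to 0.329 CPM per library. Intervals and floors cover counting error only.

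Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the groups (minimum count of 10), which left 16064 and removed 12714. The kept genes held at least 99.95% of the counts of every library. TMM factors ran from 0.771 to 1.16, and the 10 most abundant genes took 1.67 to 7.63% of counts. All 44 libraries entered a quasi-likelihood fit with a mean per group and robust dispersion, since 2 libraries per group leave too few degrees of freedom alone, and 22 residual degrees of freedom remained. Contrasts compared adjacent WT stages, WT stages 6 to 9 with stage 3, each injected group with WT of its stage, rescue with E2F1 MO, double MO with each single MO, and the single MOs with each other. The interaction and the differences of effects between stages were contrasts of the same fit. P-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. The method was tested on simulated counts with 200 changed genes, 50 at each fold. In the setting of E2F1 MO against WT at stage 7, 66, 78, 94 and 100% of genes changed 1.3-, 1.5-, 2- and 4-fold were recovered, with 8 false calls. At stage 6 the shares were 52, 72, 84 and 100%, with 7 false calls.

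CPM values are counts scaled by edgeR's cpm function to the TMM-adjusted library size, given as mean ± SD over the 2 libraries. Where all libraries of a group held 0 counts, the fold is a lower bound computed against 3 counts over the group. Where a group held 1 to 3 counts, levels are given, or the ratio with its 95% counting interval. Medians of lists are also given with such genes set at their bound.

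Gene lists were fixed before the data were examined, as were the groups, the comparisons, the tests, the rule for named genes and the alternatives. The lists were early mesendoderm and organizer genes, epidermis and BMP-responsive genes, neural plate genes, mesoderm and muscle genes, OTX-associated head and organizer genes, oocyte and germ plasm genes, DNA replication genes, mitosis genes, ribosomal protein genes, innate immune genes, p53 response genes, heat-shock and immediate early genes, adult blood, liver and ovarian follicle genes, and replication-dependent histone genes. A list of mitochondrially encoded genes was also fixed, but none of its names matched a tested gene, so it was not analysed here. Zygotic lists were set from WT libraries as genes higher at stage 7, 8 or 9 than at stage 3, with low levels before, and a maternal list likewise. A zygotic list was not tested in comparisons that use the WT stage it was chosen at. Lists were tested with camera (preset correlation of 0.01, and with an estimated correlation), with fry beside it, and adjusted over 570 tests of list and comparison. Of these, 167 were called with the preset correlation, 83 with the estimated one and 82 with both in the same direction. A further 86 list tests of differences between stages were adjusted apart from these.

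The rule for named genes took e2f1 and otx1, the 10 largest rises and falls among called genes with a real symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups, and up to 4 called members of each list by absolute change. Text space allows part of these. The 3 largest rises and falls of each comparison are given, and the 2 leading members of each list called there and of the DNA replication list. These depths were set after the values were seen, at the same number for every comparison. Genes given outside the rule are said to be so. Some genes that the rule names are not reported here.

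Alternatives were DESeq2 1.42.0, RLE factors, total counts alone, no filter on low counts, a fit with only the libraries of the comparison, the replicate number as a block, leaving out each library in turn, other thresholds for the zygotic lists, a level filter for the relation of the knockdowns and a stricter threshold for the rescued genes. When a group was left with 1 library, that library was assumed to vary like the other groups. A comparison with each of WT stages 6 to 9 was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6).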

Results

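Messenger RNA was measured in whole embryos of the western clawed frog Xenopus tropicalis from the 4-cell stage to stage 13. The series title names E2f1 and Otx1 as maternal factors acting on the earliest zygotic transcription. E2f1 is a transcription factor of the cell cycle and Otx1 a homeodomain transcription factor of head development. Untreated wild-type (WT) embryos covered stages 3 to 10 and stage 13. Stages 3, 4 and 5 are the 4-, 8- and 16-cell embryos by the sample titles. Embryos given an E2F1 morpholino (E2F1 MO; a synthetic antisense oligomer) covered stages 3 to 8. E2F1 rescue embryos received the morpholino with E2F1 mRNA and were collected at stages 6, 7 and 8. OTX1 MO embryos and embryos given both morpholinos (double MO) were collected at stages 7 and 8. Each of the 22 groups held 2 libraries, which makes 44 in all. Total counts per library ran from 9266500 to 37174000, with a median of 20542000. WT stage 10 was the shallowest group, with totals of 14569128 and 9266513. WT stage 7 held 31065046 and 31220148 and WT stage 8 held 17136933 and 14702381. Of 28778 genes, 16064 had enough counts to be tested. The spread between replicates corresponded to a biological coefficient of variation of 6.11%. The labels do not say that the 2 libraries of a group came from separate clutches, so p-values measure only the spread between these libraries, which may be technical. No group received a control morpholino.

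The RNA of the targeted genes was examined first. In WT embryos e2f1 stood at 651 ± 6.88 CPM (counts scaled to library size; mean ± SD, n = 2) at stage 3, at 493 ± 2.80 at stage 7 and at 488 ± 15.1 at stage 8. This decline depended on the scaling, as the log2 changes against stage 3, -0.40 and -0.41, turned to 0.10 and 0.12 with total counts alone and were then not called. Between stages 9 and 10 it fell from 374 ± 20.7 to 23.7 ± 6.10 CPM, a log2 change of -4.01 (edgeR adjusted p = 7.2e-19), and it stood at 41.5 ± 3.86 at stage 13. In E2F1 MO embryos e2f1 RNA was at 626 ± 28.6, 591 ± 1.5, 504 ± 6.95 and 449 ± 2.64 CPM at stages 3 to 6, and none of these differed from WT (adjusted p of 0.89 or more). At stages 7 and 8 it stood at 408 ± 6.73 and 408 ± 5.17 CPM, with log2 changes of -0.27 (adjusted p = 0.034) and -0.26 (adjusted p = 0.041). Both calls rested on all 4 libraries of their comparison. Without WT stage 7 replicate 1 or 2, or E2F1 MO stage 7 replicate 1 or 2, the adjusted p was 0.093, 0.11, 0.13 and 0.086. Without the same libraries of stage 8 it was 0.076, 0.17, 0.14 and 0.10, and with total counts alone as scaling 0.069. A morpholino acts on the translation or splicing of its target, so the level of e2f1 RNA is not a measure of the knockdown. In rescue embryos e2f1 reached 23889 ± 1092, 32498 ± 325 and 30065 ± 7486 CPM at stages 6, 7 and 8. These levels were 53.2-, 79.6- and 73.7-fold above E2F1 MO (adjusted p of 6.7e-20, 5.5e-22 and 1.2e-21). The gene took 2.25 to 3.91% of all counts in the rescue libraries, against at most 0.0561% elsewhere.

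RNA of otx1 was higher than in WT in every injected group at stages 7 and 8. In WT embryos otx1 rose from 49.1 ± 3.84 CPM at stage 3 to 103 ± 3.48 at stage 7, 108 ± 4.02 at stage 8 and 123 ± 0.921 at stage 9. It was 145 ± 0.892 and 171 ± 2.50 CPM in E2F1 MO embryos at stages 7 and 8 (log2 changes of 0.49 and 0.66, adjusted p of 2.9e-05 and 2.2e-07). OTX1 MO embryos held 168 ± 3.44 and 185 ± 5.03 CPM (0.70 and 0.78, adjusted p of 4.9e-08 and 5.7e-09). Double MO embryos held 187 ± 29.5 and 202 ± 9.41 CPM (0.86 and 0.90, adjusted p of 6.3e-10 and 2.1e-10). At stages 3 to 6 otx1 in E2F1 MO embryos stood between 53.7 and 91.9 CPM and did not differ from WT (adjusted p of 0.54 or more). The effect at stage 7 exceeded that at stage 6 by 0.46 (adjusted p = 0.0069). In rescue embryos otx1 was at 92.2 ± 13.8, 135 ± 0.584 and 146 ± 4.22 CPM at stages 6 to 8, above WT at stages 7 and 8 (0.39 and 0.44, adjusted p of 9.1e-04 and 1.5e-04). Against E2F1 MO only the stage 8 change was called (-0.22, adjusted p = 0.046), and not after leaving out E2F1 MO replicate 1 or 2 or rescue replicate 1 or 2 (0.10, 0.16, 0.24 and 0.081). OTX1 MO embryos held e2f1 at 419 ± 12.3 and 387 ± 6.40 CPM, with log2 changes of -0.23 (adjusted p = 0.066) and -0.34 (adjusted p = 0.0082, or 0.055 without WT stage 8 replicate 2). Double MO embryos held 375 ± 36.1 and 355 ± 5.43 CPM, with changes of -0.40 (adjusted p = 0.0025, or 0.062 without double MO stage 7 replicate 2) and -0.46 (adjusted p = 5.7e-04).

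**Figure D1:**
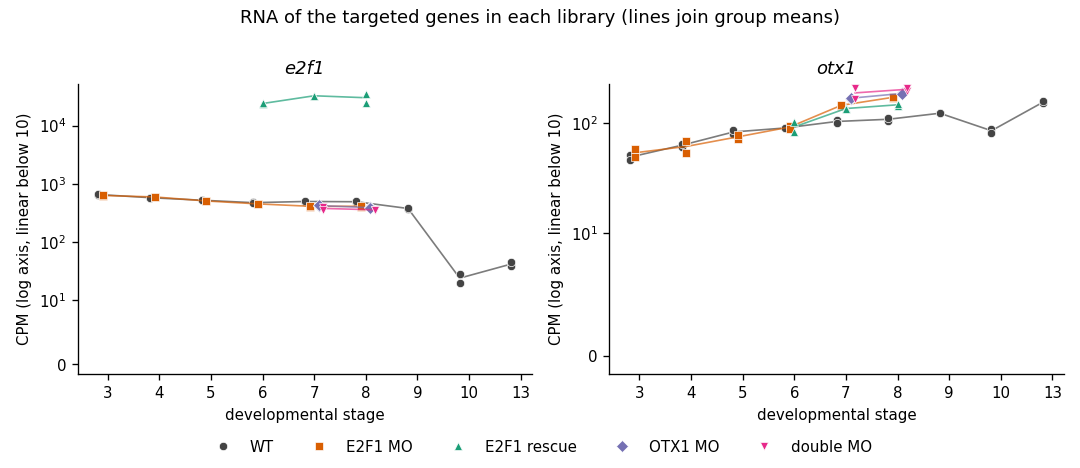
CPM of e2f1 and otx1 in each of the 44 libraries (points) against developmental stage, on a log axis that is linear below 10, with lines joining the group means. E2F1 rescue libraries stand at about 23889 to 32498 CPM for e2f1 in group means, and otx1 in all knockdown groups of stages 7 and 8 stands above the WT libraries of the same stage.

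The WT series shows when zygotic genes became detectable. Early mesendoderm and organizer genes, which encode nodal ligands, BMP antagonists and germ-layer transcription factors, stood below 1 CPM at stage 7 in all but 3 of the 37 measured members. At stage 8, 25 members were higher than at stage 3 and 2 were lower (26 and 2 adjusted over the list alone; camera adjusted p = 4.8e-05). At stage 9, 33 were higher and 1 lower (34 and 1 adjusted over the list alone; adjusted p = 4.4e-09). At stage 7 only 3 rose and 2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.95). The nodal ligand genes nodal3.1 and nodal6 went from 0 at stage 3 to 13.1 ± 1.35 and 12.1 ± 0.493 CPM at stage 8, at least 140- and 130-fold higher. The homeobox gene mix1 and admp, which encodes a BMP-related ligand of the organizer, stood at 58.2 ± 6.71 and 49.4 ± 3.21 CPM at stage 9, at least 621- and 534-fold above stage 3. Other abundant zygotic RNAs were znf33b, dab1 and sbk1l, at 51.5 ± 1.41, 51.9 ± 2.74 and 25.2 ± 1.43 CPM at stage 8 and at 0 at stage 3. Znf33b, sbk1l and ventx2.1 reached 126 ± 0.929, 116 ± 7.70 and 98.1 ± 1.56 CPM at stage 9.

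Ectodermal and mesodermal lists were tested in the same way. Of 35 epidermis and BMP-responsive genes 16 rose and 4 fell at stage 8 (16 and 4 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.18 with an estimated correlation), and 22 rose and 5 fell at stage 9 (22 and 5; adjusted p = 0.0013). Ventx2.2, a homeobox repressor downstream of BMP signalling, and foxi4.2 stood at 23.6 ± 2.10 and 12.8 ± 1.21 CPM at stage 8 and at 0 at stage 3. Neural plate and mesoderm genes were not called at stage 8 (adjusted p of 0.19 and 0.49), with 14 and 12 higher and 3 and 4 lower (14 and 11 higher and 3 and 4 lower adjusted over the list alone). Neural plate genes rose at stage 9, with 16 higher and 3 lower of 26 (16 and 3 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation). The LIM homeobox gene lhx5 and irx1 reached 68.9 ± 1.05 and 49.9 ± 1.17 CPM. Of 35 mesoderm and muscle genes 21 rose and 5 fell at stage 9 (21 and 5; adjusted p = 0.032), among them the ligand genes fgf8 and wnt8a at 28.4 ± 0.415 and 10.7 ± 0.766 CPM. Of 23 OTX-associated head and organizer genes 15 rose and 0 fell at stage 8 (15 and 0; adjusted p = 0.0062, and adjusted p = 0.14 with an estimated correlation), and 21 rose and 0 fell at stage 9 (21 and 0; adjusted p = 9.7e-06). Foxa4 of this list went from 0 to 2.80 ± 0.148 CPM at stage 8 and 28.0 ± 1.88 at stage 9.

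Cell-cycle, ribosomal protein and oocyte lists were followed over the same stages. Of 53 mitosis genes 13 rose and 36 fell at stage 7 against stage 3 (13 and 37 adjusted over the list alone; adjusted p = 3.0e-06), and 14 rose and 37 fell at stage 8 (14 and 37; adjusted p = 1.3e-06). With an estimated correlation these calls were lost (adjusted p = 0.15 and adjusted p = 0.13). The kinesin gene kif11 and the kinase gene aurka fell from 1046 ± 35.2 and 895 ± 11.1 CPM to 82.4 ± 0.224 and 80.1 ± 4.29 at stage 8, whereas the cyclin gene ccnb3 rose from 4.31 ± 1.61 to 31.6 ± 2.07 CPM at stage 7. Of 83 DNA replication genes, the classical E2F targets, 32 rose and 43 fell at stage 8 (32 and 43 adjusted over the list alone), and the list test was not called (adjusted p = 0.17). It was called lower at stage 8 against 7, with 12 risen and 36 fallen (12 and 38 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.58 with an estimated correlation). Mybl2 rose from 49.6 ± 2.07 to 429 ± 1.32 CPM and the methyltransferase gene dnmt1 fell from 6113 ± 339 to 711 ± 3.74. Ribosomal protein genes fell at stage 8, with 59 lower and 4 higher of 80 (60 and 4 adjusted over the list alone; adjusted p = 7.2e-07, and adjusted p = 0.62 with an estimated correlation). Rps26 went from 43.8 ± 0.685 to 12.9 ± 1.01 CPM. Of 40 oocyte and germ plasm genes 8 rose and 22 fell at stage 7 (8 and 22; adjusted p = 0.034, and adjusted p = 0.46 with an estimated correlation). Btg4, which promotes maternal RNA decay, fell by 2.36 on the log2 scale, and zar1 rose by 1.88. With total counts alone as scaling, log2 changes against stage 3 shifted by a median of 0.50 at stage 7, 0.53 at stage 8 and 0.56 at stage 9. Directions of lists with smaller changes, the oocyte list among them, are relative to that shift.

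Counts of genes called between successive WT stages ran from 1415 to 12349. There were 1415 calls at stage 4 against stage 3 (633 higher, 782 lower), 4382 at stage 5 against 4, 1795 at stage 6 against 5, 7540 at stage 7 against 6, 7092 at stage 8 against 7 and 3931 at stage 9 against 8. Stage 10 against 9 gave 10153 and stage 13 against 10 gave 12349. Against stage 3 there were 7726, 10108, 10545 and 11436 calls at stages 6, 7, 8 and 9. The smallest counts depended on single libraries. Stage 4 against 3 gave 519 to 793 calls without any 1 of WT stage 3 replicates 1 and 2 and WT stage 4 replicates 1 and 2. Stage 5 against 4 gave 2919 without WT stage 5 replicate 2, and stage 6 against 5 gave 700 to 1010 without any 1 of its 4 libraries (WT stage 5 and stage 6, replicates 1 and 2). The share of calls that were higher was 44.7% for stage 4 against 3, or 85.1% with total counts alone. It was 47.9% and 78.9% for stage 5 against 4, and 53.6% and 83.7% for stage 6 against 5 (42.3% with RLE factors, 41.2% with DESeq2). Several RNAs were missing altogether from some WT groups. Neil3, a DNA glycosylase gene, stood at 195 ± 2.48 CPM at stage 3 and at 0 at stages 7 and 8, at least 4440-fold lower at stage 7. Nostrin and slc6a14.1, an amino acid transporter gene, stood at 81.8 ± 8.28 and 22.7 ± 1.33 CPM at stage 3, at 0 at stage 7, and at 38.1 ± 1.81 and 58.5 ± 2.39 CPM at stage 8. Mc5r, muc2 and plcxd2 went the other way, with 6.57 ± 0.762, 23.1 ± 3.80 and 9.96 ± 0.419 CPM at stage 7 against 0, 0.308 ± 0.0723 and 0.156 ± 0.0515 at stage 3.

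**Figure D2:**
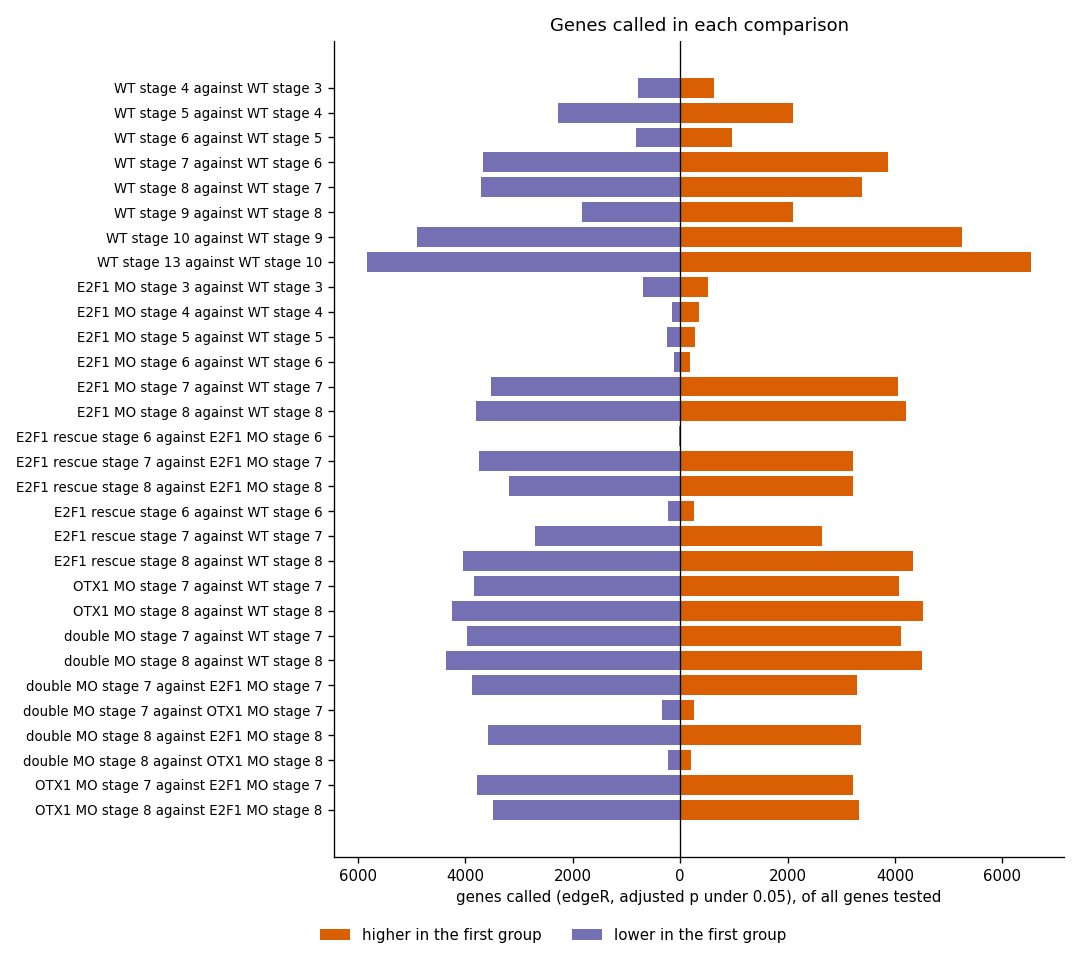
Number of genes called in each comparison (edgeR, adjusted p under 0.05, 16064 genes tested), with genes higher in the first group to the right of 0 and lower genes to the left. E2F1 MO against WT gives 313 to 1213 calls at stages 3 to 6 and 7589 and 8004 at stages 7 and 8.

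E2F1 MO embryos of the cleavage stages differed from WT in a recurring set of genes. Snapc4, a subunit of the complex that activates transcription of small nuclear RNA genes, was the largest rise at each of stages 3 to 6. It stood at 15.2 ± 2.71, 19.4 ± 2.47, 29.9 ± 2.0 and 32.9 ± 3.74 CPM against 2.88 ± 0.0116, 4.49 ± 0.148, 7.33 ± 0.710 and 10.5 ± 0.379 in WT (n = 2 each). Tmem203 was the largest fall at each of these stages, at 3.64 ± 0.194, 3.02 ± 1.25, 2.47 ± 0.537 and 3.43 ± 0.417 CPM against 13.2 ± 1.05, 13.9 ± 0.177, 14.4 ± 1.83 and 16 ± 2.64. Arpc3, a subunit of the actin-nucleating Arp2/3 complex, fell by 1.67, 1.68, 2.22 and 1.97 on the log2 scale. Other large rises were usf2 at stage 3 (1.83), sptan1 and nle1 at stage 4 (1.75 and 1.54), and sptan1 and usf2 at stage 6 (1.36 and 1.26). Other large falls were ppia at stage 3 (-1.45), the transcription factor gene myb at stage 4 (-1.81), the actin-severing gelsolin gene gsn at stage 5 (-1.94) and cops6 at stage 6 (-1.38). Each of these had an adjusted p of 3.9e-06 or less and kept its call without any 1 library. That was not so for chn2 at stage 3 (1.81, adjusted p = 0.0013), lost without E2F1 MO replicate 1 (adjusted p = 0.081) or WT replicate 1 (0.062) and at 2.44 without WT replicate 2. At stage 5 tp63 (1.79, adjusted p = 0.0092) was lost without E2F1 MO replicate 2 (0.20) or WT replicate 1 (0.17) and stood at 2.50 without WT replicate 2. Fbn3 (1.52, adjusted p = 0.049) was lost without E2F1 MO replicate 2 (0.79, log2 change 0.56), WT replicate 1 (0.38) or WT replicate 2 (0.11).

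In all, 1213 genes were called at stage 3 (523 higher, 690 lower), 503 at stage 4 (347 and 156), 521 at stage 5 (268 and 253) and 313 at stage 6 (189 and 124). Of these, 74, 70, 43 and 32 differed by 2-fold or more. Single libraries moved these counts. Stage 3 gave 514, 696 and 263 calls without WT replicate 1, WT replicate 2 or E2F1 MO replicate 1. Stage 4 gave 249, 205 and 198 without WT replicate 1, WT replicate 2 or E2F1 MO replicate 1. Stage 5 gave 257 to 291 without any 1 of its 4 libraries (WT and E2F1 MO, replicates 1 and 2), and stage 6 gave 159, 183 and 174 without WT replicate 1, WT replicate 2 or E2F1 MO replicate 2. The share of higher calls at stage 3 was 43.1%, or 71.6% with total counts alone and 64.9% with fewer libraries in the fit. At stage 4 it was 69.0%, or 79.0% with total counts alone, 55.2% with RLE factors, 54.2% with fewer libraries and 46.3% with DESeq2. Genes called in the same direction at stages 3, 4 and 5 numbered 128 higher and 48 lower, against 0.188 and 0.106 if the 3 lists were independent. At stage 6, which shares no library with those stages, the 128 genes had a median change of 0.41 with 103 called higher, and the 48 genes a median of -0.52 with 39 called lower.

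**Figure D3:**
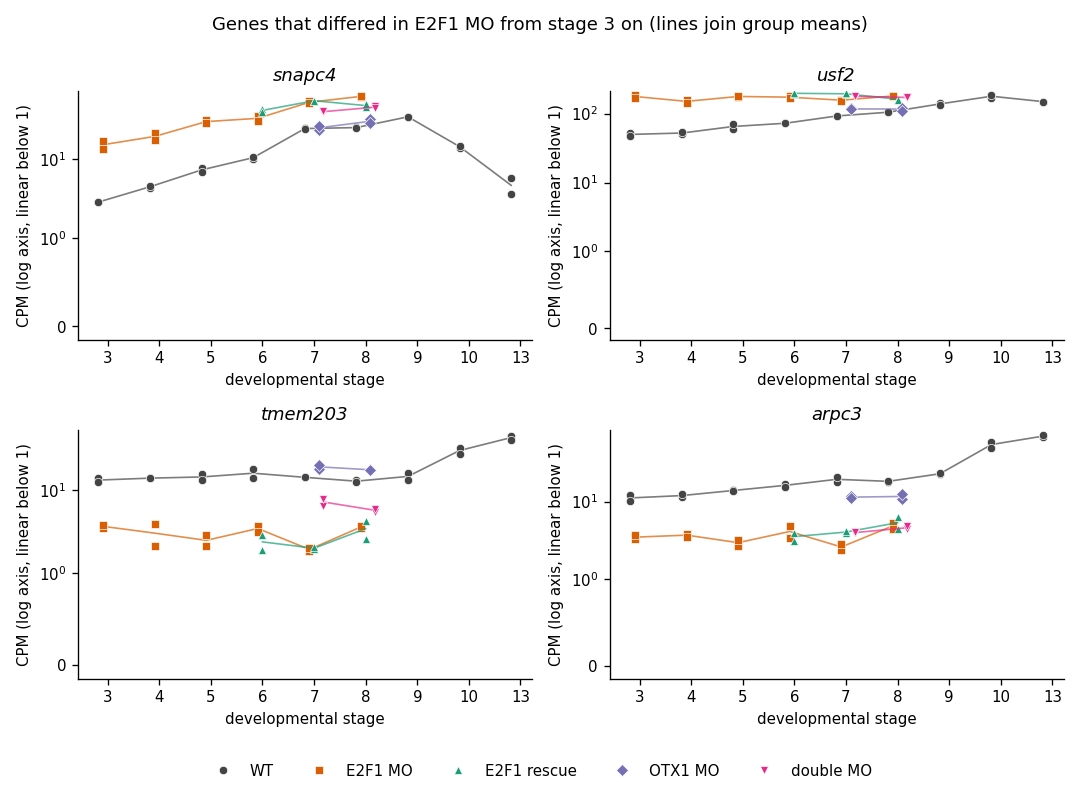
CPM of snapc4, usf2, tmem203 and arpc3 in each library (points) against developmental stage, on a log axis that is linear below 1, with lines joining the group means. From stage 3 on, E2F1 MO libraries lie above WT for snapc4 and below WT for tmem203 and arpc3, and E2F1 rescue libraries lie with E2F1 MO.

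Early mesendoderm genes were mostly below detection in embryos of the cleavage stages. At stages 3 to 6 only 3 of the 37 stood at 1 CPM or more in WT and in E2F1 MO, so a fall could not be seen in the others. In E2F1 MO against WT edgeR called 0 of the 37 at stages 3, 4, 5 and 6, with 1, 2, 3 and 2 at an unadjusted p under 0.05 and 0 by DESeq2 at each stage. DNA replication genes moved in both directions. At stage 3, 5 rose and 10 fell (6 and 19 adjusted over the list alone; camera adjusted p = 0.058), with rpa1, the large subunit of the single-strand DNA binding complex, up by 0.98 and pole2 down, from 153 ± 34.9 to 79.4 ± 0.104 CPM. Rpa1 was also higher at stages 4, 5 and 6 (1.01, 0.92 and 0.97), while mcm3 fell by 0.51 at stage 5. Orc5 was higher at stages 4 and 6 (0.50 and 0.41), a call lost at stage 4 without WT replicate 2 (adjusted p = 0.11) and at stage 6 without WT replicate 1 (0.10), WT replicate 2 (0.14) or E2F1 MO replicate 2 (0.29). Ribosomal protein genes were lower at stage 3, with 22 fallen and 0 risen of 80 (38 and 0 adjusted over the list alone; adjusted p = 4.8e-12, and adjusted p = 0.41 with an estimated correlation) and a median of -0.30. Rpl18 of this list fell by 0.67, 0.82 and 0.61 at stages 3, 5 and 6. Rpl36a fell from 4.69 ± 0.467 to 2.43 ± 0.914 CPM at stage 3, lost without WT replicate 1 (0.066), WT replicate 2 (0.17) or E2F1 MO replicate 1 (0.43). At stage 5, 0 ribosomal protein genes rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.76 with an estimated correlation), and rps15a (-0.43) lost its call without any of the WT or E2F1 MO replicates 1 and 2 (0.27, 0.13, 0.23 and 0.18).

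Calls of the mitosis and oocyte lists in E2F1 MO embryos of the cleavage stages were all lost with an estimated correlation. At stage 3, 1 mitosis gene rose and 12 fell of 53 (2 and 18 adjusted over the list alone; adjusted p = 6.0e-04, and adjusted p = 0.34 with an estimated correlation). Of 40 oocyte and germ plasm genes 0 rose and 12 fell (0 and 16; adjusted p = 1.1e-04, and adjusted p = 0.11 with an estimated correlation). Pkmyt1 (-0.39) and mad2l1 (-0.33) of the former, and figla (-0.55) and zp4.2 (-0.53) of the latter, were called at stage 3. None of these 4 kept its call without every library. Without E2F1 MO replicate 1 the adjusted p of pkmyt1, mad2l1, figla and zp4.2 was 0.052, 0.094, 0.27 and 0.22. Without WT replicate 1 it was 0.052 for mad2l1, 0.056 for figla and 0.37 for zp4.2, without WT replicate 2 0.21 for pkmyt1, and without E2F1 MO replicate 2 0.16 for pkmyt1 and 0.074 for zp4.2. At stage 4 the mitosis list (2 rose and 2 fell, 2 and 3 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation) was not called without WT replicate 1 or E2F1 MO replicate 1 (unadjusted p = 0.017 and 0.11) or with total counts alone (0.055). Its kif11 (-0.32) and mad2l1 (-0.35) lost their calls without E2F1 MO replicate 1 (adjusted p = 0.37 and 0.28), kif11 also without WT replicate 1 (0.075) and mad2l1 without WT replicate 2 (0.11). At stage 5 neither list was called (adjusted p of 1.0 and 0.13), with 0 risen and 1 and 2 fallen (0 and 1 risen and 1 and 3 fallen adjusted over the list alone). At stage 6 the mitosis, oocyte and ribosomal lists were called lower (adjusted p of 0.0035, 0.0038 and 0.034, and adjusted p = 0.46, adjusted p = 0.25 and adjusted p = 0.86 with an estimated correlation), with 3, 1 and 2 genes fallen and 0, 1 and 0 risen (5, 4 and 2 fallen and 0, 1 and 0 risen adjusted over the list alone). Pkmyt1, kif11 and velo1 fell by 0.45, 0.42 and 0.47. The oocyte call was lost without WT stage 6 replicate 1 (unadjusted p = 0.057), and the ribosomal call without that library (0.054) or E2F1 MO replicate 2 (0.84). Piwil2 (0.76) and rpl15 (-0.31) lost their calls without WT replicate 1 (0.14 and 0.29), WT replicate 2 (0.060 and 0.14) or E2F1 MO replicate 2 (0.20 and 0.43), and rpl15 also without E2F1 MO replicate 1 (0.058).

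At stage 7 E2F1 MO embryos held early zygotic RNAs that WT embryos of that stage lacked. Of the 37 early mesendoderm and organizer genes 28 were higher and 1 lower (28 and 1 adjusted over the list alone; camera adjusted p = 5.0e-13). The median log2 change was 5.29, or 3.46 with genes at 0 set to their bound. Members at 1 CPM or more numbered 20 in E2F1 MO and 3 in WT. Foxd4l1.1 and the BMP antagonist gene chordin (chrd.1) stood at 2.82 ± 0.0653 and 2.13 ± 0.10 CPM and at 0 in WT, at least 64.3- and 48.6-fold higher. The siamois gene sia2, nodal3.1, ventx2.2 and admp reached 9.92 ± 1.10, 8.16, 19.9 ± 1.73 and 11.5 ± 0.987 CPM against 0.248, 0.132, 0.0146 and 0.0293 in WT. Sia2 and nodal3.1 were chosen here after their values were seen. At stage 8 WT embryos held the same 4 RNAs at 10.4, 13.1, 23.6 and 11.9 CPM.

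Genes of the later germ layers rose with them. Of 35 epidermis and BMP-responsive genes 18 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 2.9e-04), with a median of 0.31, or 0.28 with genes at 0 set to their bound. Ventx2.1 stood at 3.56 ± 0.321 CPM and at 0 in WT, and the ratio for ventx2.2 was 1367 with a 95% counting interval of 245 to 54026. Of 26 neural plate genes 16 rose and 2 fell (17 and 3; adjusted p = 2.9e-04; median 2.71, or 1.63 with bounds). Irx1 and lhx5 stood at 5.94 ± 0.110 and 1.21 ± 0.248 CPM against 0.0146 ± 0.0206 and 0. Of 35 mesoderm and muscle genes 19 rose and 2 fell (20 and 2; adjusted p = 4.4e-04; median 1.06, or 0.74 with bounds), led by fgf8 and fgf20, at least 46.9- and 39.1-fold higher. Of 23 OTX-associated head and organizer genes 15 rose and 0 fell (16 and 0; adjusted p = 8.6e-06; median 3.38, or 3.29 with bounds), with lhx5 and the forebrain gene six3 at least 27.3- and 25.9-fold higher. These 5 calls held with an estimated correlation (adjusted p between 4.8e-05 and 0.035). The OTX-associated and early mesendoderm lists overlap, with 18 of 23 and 15 of 37 genes shared with another list.

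**Figure D4:**
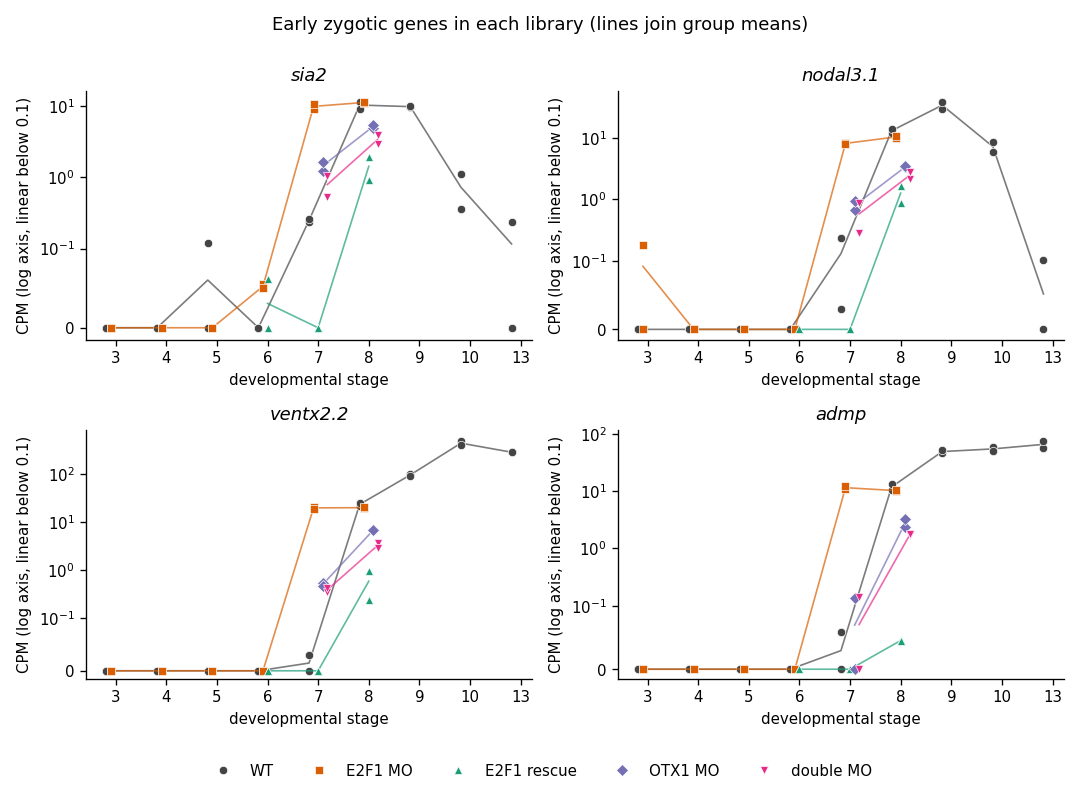
CPM of sia2, nodal3.1, ventx2.2 and admp in each library (points) against developmental stage, on a log axis that is linear below 0.1, with lines joining the group means. At stage 7 E2F1 MO libraries stand at 8.16 to 19.9 CPM in group means while WT libraries stand below 0.3, and at stage 8 rescue, double MO and OTX1 MO libraries lie below WT.

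Most ribosomal protein genes went down in E2F1 MO embryos at stage 7. Of 80 ribosomal protein genes 55 fell and 6 rose (56 and 6 adjusted over the list alone; adjusted p = 4.5e-10, and adjusted p = 0.49 with an estimated correlation; median -0.56). Rpl37 and rpl29 stood at 2.17 ± 0.147 and 2.32 ± 0.533 CPM against 10.4 ± 0.377 and 8.62 ± 0.98. Mitosis genes split into 15 higher and 25 lower (16 and 26; adjusted p = 0.019, and adjusted p = 0.58 with an estimated correlation). Cks1b and cks2, subunits of cyclin-dependent kinases, fell by 2.45 and 2.19. DNA replication genes divided evenly, with 27 higher and 25 lower (27 and 26 adjusted over the list alone; adjusted p = 0.66). Brca2 rose from 44.1 ± 1.06 to 116 ± 2.78 CPM and the sliding clamp gene pcna fell from 74.1 ± 0.629 to 31.9 ± 0.742. The largest rises were neil3 and slc6a14.1, at 73.3 ± 1.66 and 33.0 ± 0.634 CPM and at 0 in WT, and lingo4 at 8.97 ± 0.214. These were at least 1676-, 754- and 205-fold higher. The largest falls were lad1, fibcd1 and cdr2l, at 6.70 ± 0.162, 6.17 ± 0.825 and 10.5 ± 0.512 CPM in WT and at 0.0147 ± 0.0208, 0.0147 ± 0.0208 and 0.0607 ± 0.0393 in E2F1 MO. The log2 change of cdr2l was -7.28, or -8.09 without E2F1 MO replicate 1. In all, 7589 genes were called (4062 higher, 3527 lower), 2289 of them by 2-fold or more. Leaving out any 1 library moved this count by less than 1.5 times. Against each of WT stages 6, 7, 8 and 9 in the same direction, a comparison added after seeing the data, 2818 of the calls remained.

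At stage 8 the early zygotic lists no longer stood above WT. Of the early mesendoderm genes 1 was higher and 7 lower (1 and 6 adjusted over the list alone; adjusted p = 0.26). Sia2, nodal3.1, ventx2.2 and admp, followed here after their values were seen, stood at 11.3, 10.4, 20.1 and 10.2 CPM against 10.4, 13.1, 23.6 and 11.9 in WT. The epidermis, neural, mesoderm and OTX-associated lists had 8, 4, 7 and 2 genes higher and 9, 3, 5 and 6 lower (8, 4, 6 and 2 higher and 10, 3, 5 and 5 lower adjusted over the list alone), and none was called (adjusted p of 0.66, 0.92, 0.90 and 0.39). The change in effect between the stages was itself tested. It was lower at stage 8 for 25 of the 37 early mesendoderm genes and higher for 0 (25 and 0 adjusted over the list alone; adjusted p = 5.1e-15). Ribosomal protein genes turned upward, with 41 higher and 11 lower (42 and 11; adjusted p = 0.0048, and adjusted p = 0.82 with an estimated correlation). Rpl36 and rpl35a stood at 19.0 ± 1.92 and 5.22 ± 0.729 CPM against 7.36 ± 1.32 and 2.10 ± 0.190. The difference between stages was positive for 57 of the 80 and negative for 2 (57 and 2; adjusted p = 5.0e-14, and adjusted p = 0.34 with an estimated correlation). Of DNA replication genes 34 were higher and 22 lower (34 and 22; adjusted p = 0.38). Rrm1, the large subunit of ribonucleotide reductase, and rpa1 rose from 48.8 ± 3.24 and 41.4 ± 1.12 CPM to 152 ± 0.580 and 125 ± 2.28.

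**Figure D5:**
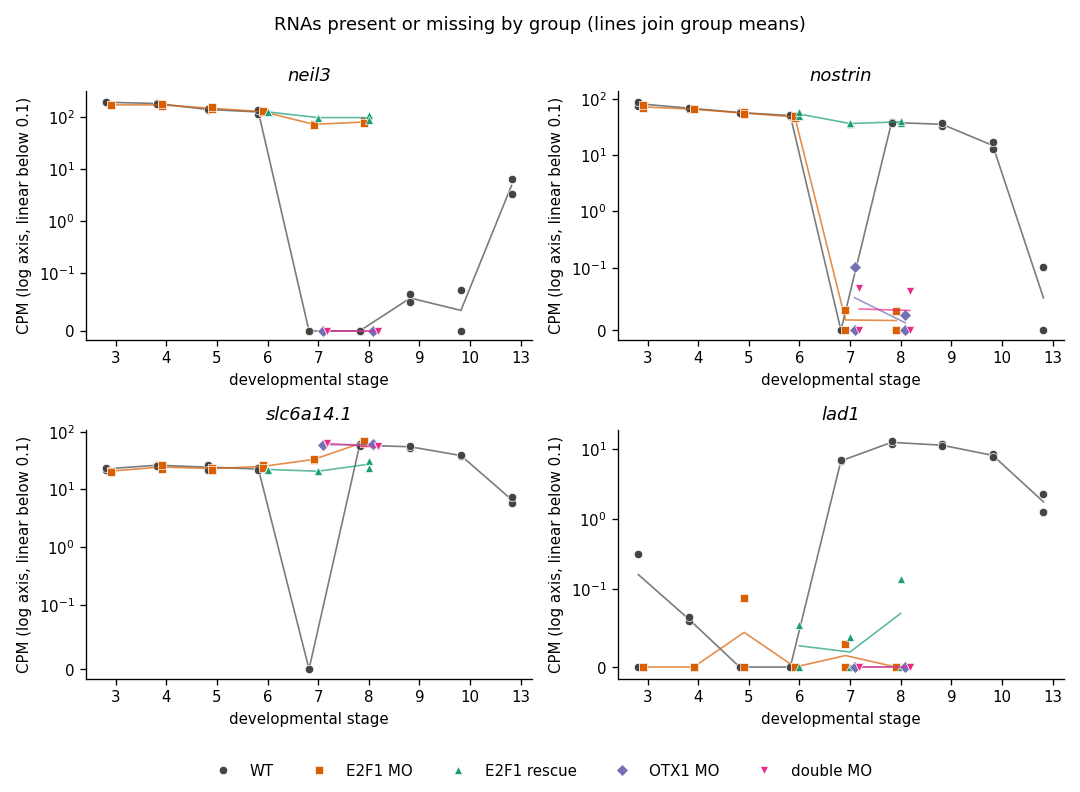
CPM of neil3, nostrin, slc6a14.1 and lad1 in each library (points) against developmental stage, on a log axis that is linear below 0.1, with lines joining the group means. Neil3 stands at 73.3 and 80.9 CPM in E2F1 MO at stages 7 and 8 and at 0 in WT, OTX1 MO and double MO libraries of those stages, and slc6a14.1 is missing from WT stage 7 alone.

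The largest rises at stage 8 were neil3, col14a1 and pdgfd, at 80.9 ± 3.75, 13.7 ± 0.549 and 7.69 ± 0.658 CPM and at 0 in WT, at least 966-, 163- and 91.7-fold higher. The largest falls were lad1, the cytokine gene il34 and nostrin, at 12.3 ± 0.750, 11.7 ± 1.51 and 38.1 ± 1.81 CPM in WT. Lad1 and il34 stood at 0 in E2F1 MO, at least 262- and 248-fold lower, and nostrin at 0.0155 ± 0.0219. In all, 8004 genes were called (4202 higher, 3802 lower), 2434 by 2-fold or more, and 2349 lay beyond each of WT stages 6 to 9. The E2F1 MO effect differed between stages 8 and 7 in 6269 genes and between stages 7 and 6 in 4739. Genes called in both stages agreed in direction for 1983 higher and 1542 lower and were opposite for 1267, against 1063, 835 and 1884 if the lists were independent.

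Rescue was compared with E2F1 MO, whose clutch may differ. Early zygotic RNAs were lower in rescue at stages 7 and 8, but E2F1 MO had exceeded WT only at stage 7. Of the early mesendoderm genes 0 rose and 25 fell at stage 7 (0 and 26 adjusted over the list alone; adjusted p = 2.4e-13; median -4.96, or -3.28 with bounds), and 1 rose and 26 fell at stage 8 (1 and 26; adjusted p = 5.0e-13; median -3.50, or -2.82 with bounds). Admp and sia2 stood at 0 in rescue at stage 7, at least 205- and 176-fold lower, and admp at 0.0451 ± 0.000971 CPM at stage 8. Foxa4 was at 0 at stage 8, at least 20.5-fold lower. Epidermis genes fell in the same way, with 18 and 16 lower and 4 and 3 higher at stages 7 and 8 (18 and 16 lower and 5 and 4 higher adjusted over the list alone; adjusted p of 0.0011 and 3.0e-04). Ventx2.2 and ventx2.1 stood at 0 at stage 7, at least 355- and 63.2-fold lower, and foxi1 and tfap2a at 0 at stage 8, at least 27.2- and 22.6-fold lower. Of neural plate genes 12 and 13 fell and 3 and 1 rose (the same counts adjusted over the list alone; adjusted p of 0.0049 and 1.9e-04). At stage 7 this call was lost with an estimated correlation (adjusted p = 0.11). Irx1 and irx2 stood at 0 at stage 7, and irx1 and foxb1 at 0.0222 ± 0.0314 and 0 CPM at stage 8. Of mesoderm genes 18 and 16 fell and 4 and 3 rose (18 and 17 fell and 4 and 4 rose adjusted over the list alone; adjusted p of 0.012 and 0.0023), with fgf8 at 0 at both stages. Of OTX-associated genes 12 and 14 fell and 1 rose at each stage (13 and 14 fell and 1 rose adjusted over the list alone; adjusted p of 1.0e-04 and 1.7e-05), with foxa4 and lhx1 at 0 at stage 7 and gsc at 0.0229 ± 0.0324 CPM at stage 8.

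Ribosomal protein genes rose in rescue against E2F1 MO, with 26 and 35 higher and 5 and 2 lower at stages 7 and 8 (25 and 36 higher and 5 and 2 lower adjusted over the list alone; adjusted p of 0.0059 and 9.1e-05, and adjusted p = 0.82 and adjusted p = 0.74 with an estimated correlation). Rpl39 and rpl37a rose by 0.94 and 0.90 at stage 7, and rps12 and rpl12 by 0.96 and 0.83 at stage 8. The stage 8 call was lost without rescue replicate 1 (unadjusted p = 0.024). Of mitosis genes 23 and 26 rose and 12 and 11 fell (25 and 26 rose and 12 and 12 fell adjusted over the list alone; adjusted p of 0.0043 and 0.037, and adjusted p = 0.48 and adjusted p = 0.64 with an estimated correlation). The stage 8 call was lost without rescue replicate 2 (unadjusted p = 0.024), with RLE factors (0.021) and with total counts alone (0.042). At stage 7 ect2 fell by 1.76 and cks1b rose by 1.69. At stage 8 cdc25b rose by 1.02, and nek2 (-2.35) lost its call without E2F1 MO replicate 1 (adjusted p = 0.11) or rescue replicate 1 (0.053, log2 change -3.29) or 2 (0.15). Of 83 DNA replication genes 24 and 25 rose and 27 and 17 fell at stages 7 and 8 (24 and 28 rose and 29 and 18 fell adjusted over the list alone), and the list was not called (adjusted p of 0.59 and 0.12). Gins3 rose by 0.85 at stage 8. The largest rises at stage 7 were nostrin, espnl and tmem47, at 36.4 ± 1.39, 7.87 ± 0.592 and 5.09 ± 0.102 CPM, and the largest fall was sbk1l, from 21.2 ± 0.311 to 0. At stage 8 nostrin, the complement gene cfb and sorcs3 rose to 39.0 ± 2.89, 8.56 ± 1.11 and 13.3 ± 0.576 CPM, and ventx2.1 and sbk1l fell from 6.85 ± 0.737 and 13.8 ± 0.548 to 0.0222 ± 0.0314 and 0.0667 ± 0.0943. In all, 6969 genes were called at stage 7 (3225 higher, 3744 lower) and 6410 at stage 8 (3222 and 3188), or 4121 at stage 8 without rescue replicate 1.

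At stage 6 rescue and E2F1 MO embryos differed in 21 genes (7 higher, 14 lower). The share of higher calls was 33.3%, or 1.79% with total counts alone. Besides e2f1 the largest rises were stim1 (0.38) and rcc2 (0.32) and the largest falls rrp15 (-0.60), txlng (-0.52) and pole2 (-0.48), with adjusted p between 5.8e-04 and 0.046. These 5 calls were lost by leaving out single libraries. Without E2F1 MO stage 6 replicate 1 the adjusted p of rcc2, rrp15, txlng and pole2 was 0.12, 0.36, 0.11 and 0.25, and without its replicate 2 that of stim1, rcc2 and pole2 was 0.43, 0.37 and 0.076. Without rescue stage 6 replicate 1 that of stim1, rcc2 and pole2 was 0.15, 0.084 and 0.090, and without its replicate 2 that of stim1, rcc2, rrp15, txlng and pole2 was 0.19, 0.65, 0.63, 0.33 and 0.53. The count fell to 6, 5 and 1 without E2F1 MO replicate 1, E2F1 MO replicate 2 or rescue replicate 2. Against WT, rescue embryos differed in 484 genes at stage 6 (247 higher, 237 lower), 5349 at stage 7 (2643 and 2706) and 8378 at stage 8 (4335 and 4043). The stage 6 count was 248, 320 and 239 without WT replicate 2, rescue replicate 1 or rescue replicate 2, and its share of higher calls was 51.0%, or 31.1% with total counts alone.

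Against WT, rescue embryos held low early zygotic RNA at stage 8. Of the early mesendoderm genes 1 was higher and 27 were lower (1 and 28 adjusted over the list alone; adjusted p = 5.8e-10; median -3.60, or -2.81 with bounds), whereas 3 were higher and 3 lower at stage 7 (3 and 3; adjusted p = 0.95). Epidermis, neural plate, mesoderm and OTX-associated genes had 13, 11, 16 and 13 lower and 7, 2, 4 and 1 higher at stage 8 (13, 11, 16 and 15 lower and 7, 2, 4 and 1 higher adjusted over the list alone; adjusted p of 0.016, 0.036, 0.022 and 3.4e-04). The epidermis and neural calls were lost with an estimated correlation (adjusted p = 0.10 and adjusted p = 0.25). The neural call was also lost without WT stage 8 replicate 2 (unadjusted p = 0.031) or rescue replicate 2 (0.028), with RLE factors (0.015) and with total counts alone (0.014), and the mesoderm call without rescue replicate 2 (0.021). Ribosomal protein genes were lower at stage 7, with 46 fallen and 7 risen (47 and 7 adjusted over the list alone; adjusted p = 1.0e-06, and adjusted p = 0.62 with an estimated correlation), and higher at stage 8, with 57 risen and 6 fallen (58 and 7; adjusted p = 1.3e-07, and adjusted p = 0.58 with an estimated correlation). DNA replication genes were called higher at stage 8, with 43 risen and 19 fallen (43 and 21 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.58 with an estimated correlation), a call lost without rescue replicate 1 (unadjusted p = 0.014). The counts of this list in rescue include e2f1, the injected mRNA. Without it, an alternative added after seeing the data, 42 rose and 19 fell (42 and 21; adjusted p = 0.035, and adjusted p = 0.63 with an estimated correlation). At stages 6 and 7 they had 3 and 17 risen and 5 and 18 fallen (7 and 18 risen and 8 and 19 fallen adjusted over the list alone) and were not called (adjusted p of 0.41 and 1.0).

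The rescue of called genes was measured at a stage other than the one they were chosen at. Genes higher in E2F1 MO at stage 6 had a median change from WT at stage 7 of 0.28 in E2F1 MO and 0.30 in rescue, and genes lower at stage 6 of -0.35 and -0.44. Measured at stage 8, the same sets had medians of 0.44 in E2F1 MO and 0.41 in rescue, and of -0.23 and -0.17. Genes higher at stage 7 had medians at stage 8 of 0.28 in E2F1 MO and 0.17 in rescue, and lower genes of -0.19 and -0.10. Genes higher at stage 8 had medians at stage 7 of 0.24 and 0.07, and lower genes of -0.15 and -0.06. For the 48 lower genes of the cleavage-stage set, the median at stage 6 was -0.52 in E2F1 MO and -0.64 in rescue. Tmem203, arpc3 and snapc4 stood at 2.37, 3.55 and 41.4 CPM in rescue at stage 6 against 16, 16.2 and 10.5 in WT.

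OTX1 MO embryos lacked the early zygotic rise of E2F1 MO embryos at stage 7. Of the early mesendoderm genes 7 were higher and 1 lower than in WT (6 and 1 adjusted over the list alone; adjusted p = 0.39), and 4 stood at 1 CPM or more. At stage 8, 21 were lower and 2 higher (24 and 2; adjusted p = 1.2e-05; median -1.64, or -1.45 with bounds). Nodal2 and bix1.1 led these falls, at 0 and 0.0142 ± 0.0201 CPM against 0.147 ± 0.135 and 0.380 ± 0.318 in WT. Both are near the detection limit. Nodal2 was not called without WT stage 8 replicate 2 (adjusted p = 0.22) or OTX1 MO replicate 1 (0.073) or 2 (0.056), nor bix1.1 without WT stage 8 replicate 2 (0.12). Sia2, nodal3.1, ventx2.2 and admp, again followed after their values were seen, stood at 5.21, 3.38, 6.83 and 2.83 CPM against 10.4, 13.1, 23.6 and 11.9 in WT. Epidermis genes were lower at stage 8, with 14 fallen and 5 risen (14 and 5 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.14 with an estimated correlation). Grhl3 and tfap2a stood at 0.472 ± 0.297 and 0.427 ± 0.200 CPM against 7.95 ± 1.85 and 5.41 ± 0.393. The log2 change of grhl3 was -4.10, or -4.88 without OTX1 MO replicate 2. Of OTX-associated genes 9 fell and 1 rose (9 and 1; adjusted p = 0.018, and adjusted p = 0.21 with an estimated correlation). Lhx5 fell from 3.24 ± 0.476 to 0.216 ± 0.137 CPM (-3.94, or -4.71 without OTX1 MO replicate 2) and gsc from 1.17 ± 0.110 to 0.169 ± 0.00248. The list's call was lost without WT stage 8 replicate 2 (unadjusted p = 0.019). Neural plate and mesoderm genes had 2 and 3 higher and 7 and 13 lower (2 and 3 higher and 7 and 12 lower adjusted over the list alone) and were not called (adjusted p of 0.18 and 0.19).

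At stage 7 ribosomal protein genes were lower in OTX1 MO, with 44 fallen and 8 risen (44 and 8 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.68 with an estimated correlation), and mitosis genes had 25 fallen and 11 risen (25 and 12; adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). Rpl29 and rpl32 fell by 2.36 and 2.29, and cks2 and aurka by 1.76 and 1.44. Of DNA replication genes 24 rose and 36 fell (24 and 39; adjusted p = 0.18) at stage 7, with gins1 and rbl1 down by 1.96 and 1.33, and 30 rose and 26 fell (30 and 26; adjusted p = 0.89) at stage 8, with rbl1 down by 1.47. The largest rises at stage 7 were slc6a14.1, ccm2l and rtp3a.3, at 59.1 ± 0.464, 9.17 ± 0.613 and 10.1 ± 0.157 CPM against 0, 0.0292 ± 0.000102 and 0.0583 ± 0.0411. The log2 change of rtp3a.3 was 7.31, or 8.18 without WT stage 7 replicate 2. The largest falls were lad1, b4galnt3 and unc80, from 6.70 ± 0.162, 16.5 ± 0.397 and 5.39 ± 2.31 CPM to 0, 0.0949 ± 0.0361 and 0.0347 ± 0.0491. At stage 8 col14a1, adgre5 and pdgfd rose from 0 to 35.5 ± 2.03, 9.37 ± 0.311 and 6.51 ± 0.235 CPM, and plcxd2, lad1 and il34 fell to 0, at least 387-, 315- and 298-fold lower. In all, 7906 genes were called at stage 7 (4065 higher, 3841 lower) and 8765 at stage 8 (4517 and 4248), of which 3152 and 3625 lay beyond each of WT stages 6 to 9. The effect differed between the stages in 5110 genes.

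Double MO embryos resembled OTX1 MO embryos. Against WT the early mesendoderm list had 7 genes higher and 1 lower at stage 7 (6 and 1 adjusted over the list alone; adjusted p = 0.57) and 1 higher and 26 lower at stage 8 (2 and 26; adjusted p = 1.7e-07; median -2.41, or -2.18 with bounds). Bix1.1 and nodal1 stood at 0 against 0.380 ± 0.318 and 0.134 ± 0.104 CPM in WT, and nodal1 was not called without WT stage 8 replicate 1 (adjusted p = 0.19) or double MO replicate 1 (0.076). Of epidermis genes 15 fell and 7 rose at stage 8 (15 and 7; adjusted p = 0.032, and adjusted p = 0.15 with an estimated correlation), with foxi1 and grhl3 at 0.0629 ± 0.0442 and 0.248 ± 0.0823 CPM against 2.44 ± 0.286 and 7.95 ± 1.85. Foxi1 changed by -5.08, or -6.05 without double MO replicate 1. Of OTX-associated genes 13 fell and 1 rose (13 and 1; adjusted p = 0.0033, and adjusted p = 0.10 with an estimated correlation). Lhx5 fell to 0.102 ± 0.0552 CPM (-4.85, or -5.57 without double MO replicate 1). Ribosomal protein genes were higher at stage 8, with 37 risen and 10 fallen (37 and 10; adjusted p = 0.0052, and adjusted p = 0.82 with an estimated correlation), and rpl5 and rps4x up by 2.01 and 1.61. Of DNA replication genes 23 rose and 31 fell at stage 7 (24 and 32; adjusted p = 0.42), with gins1 and rbl1 down by 1.77 and 1.16, and 35 rose and 27 fell at stage 8 (35 and 29; adjusted p = 0.74), with mcm6.2 down by 1.84. Slc6a14.1, pdgfd and ccm2l rose most at stage 7, to 62.7 ± 1.80, 6.30 ± 1.5 and 7.84 ± 1.41 CPM, and lad1, flt3 and plcxd2 fell most, to 0, 0 and 0.0170 ± 0.0241. At stage 8 col14a1, pdgfd and tmtops rose from 0 to 32.9 ± 1.17, 6.94 ± 1.23 and 6.39 ± 1.11 CPM, and asrgl1, lad1 and il34 fell from 76.3 ± 0.986, 12.3 ± 0.750 and 11.7 ± 1.51 to 0.0235 ± 0.0333, 0 and 0. In all, 8082 genes were called at stage 7 (4115 higher, 3967 lower) and 8866 at stage 8 (4497 and 4369), with 3239 and 3687 beyond each of WT stages 6 to 9. The effect differed between the stages in 5155 genes.

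Adding the E2F1 morpholino to the OTX1 morpholino changed 601 genes at stage 7 (264 higher, 337 lower; 33 by 2-fold or more) and 431 at stage 8 (203 and 228; 99). Single libraries moved both counts. Stage 7 gave 197, 214, 1264 and 172 calls without OTX1 MO replicate 1, OTX1 MO replicate 2, double MO replicate 1 or double MO replicate 2, and stage 8 gave 226, 284, 237 and 216. The share of higher calls at stage 7 was 43.9%, or 64.1% with total counts alone. Of the early mesendoderm genes edgeR called 0 at stage 7 (2 at an unadjusted p under 0.05 and 0 by DESeq2; list adjusted p = 0.55). At stage 8, 0 rose and 4 fell (1 and 12 adjusted over the list alone; adjusted p = 4.4e-09; median -0.72, or -0.55 with bounds). Sia2, nodal3.1 and ventx2.2, chosen after their values were seen, stood at 3.43, 2.48 and 3.30 CPM in double MO and 5.21, 3.38 and 6.83 in OTX1 MO. Neural plate and OTX-associated lists were also lower at stage 8, with 2 and 1 fallen and 0 risen in each (4 and 5 fallen and 0 and 1 risen adjusted over the list alone; adjusted p of 0.0091 and 0.0029, and adjusted p = 0.15 and adjusted p = 0.10 with an estimated correlation). The neural call was lost without double MO replicate 1 (unadjusted p = 0.16). Mitosis genes had 9 higher and 1 lower at stage 8 (10 and 1 adjusted over the list alone; adjusted p = 6.9e-06, and adjusted p = 0.17 with an estimated correlation). Ribosomal protein genes were higher at stage 7, with 17 risen and 0 fallen (36 and 0; adjusted p = 1.5e-19, and adjusted p = 0.21 with an estimated correlation). At stage 8, 4 ribosomal protein genes rose and 0 fell (9 and 1; adjusted p = 2.4e-06, and adjusted p = 0.65 with an estimated correlation), a call lost without OTX1 MO replicate 1 (unadjusted p = 0.018). Against E2F1 MO, double MO embryos differed in 7172 and 6941 genes at stages 7 and 8, and OTX1 MO embryos in 7002 and 6809. Early mesendoderm genes were lower in both. In double MO 25 and 23 fell and 1 and 0 rose (26 and 26 fell and 1 and 0 rose adjusted over the list alone; adjusted p of 2.4e-12 and 1.8e-09). In OTX1 MO 26 and 23 fell and 0 and 1 rose (26 and 23 fell and 1 and 1 rose adjusted over the list alone; adjusted p of 2.4e-12 and 3.8e-06).

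The interaction asks whether the effect of both morpholinos differs from the sum of their separate log2 effects. It was called for 5502 genes at stage 7 (2560 higher, 2942 lower) and 5771 at stage 8 (2661 and 3110). At stage 7 it was negative for 18 early mesendoderm genes and positive for 0 (20 and 0 adjusted over the list alone; adjusted p = 2.0e-04), and at stage 8 for 6 and 0 (5 and 0; adjusted p = 0.29). For ribosomal protein genes at stage 7 it was positive for 61 and negative for 1 (65 and 1; adjusted p = 1.7e-18, and adjusted p = 0.22 with an estimated correlation). For otx1 it was -0.33 at stage 7 (adjusted p = 0.045) and -0.54 at stage 8 (adjusted p = 0.0010).

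The log2 changes of the 2 single knockdowns were compared across genes. At stage 7 they had a correlation of 0.44 across 16064 genes, against 0.49 in 20 simulations of unchanged groups set against the same WT libraries, and 69.9% of genes had the same sign, against a simulated 69.3%. Shared controls alone give unchanged groups a correlation of this size, so it cannot decide whether the knockdowns were alike. The covariance, which depends on the size of the changes, was 0.367 against a simulated 0.0248. Simulated noise in the shared controls thus gave little of it. At stage 8 the correlation was 0.62 against 0.62, the share of the same sign 77.1% against 71.6% and the covariance 0.627 against 0.0405. Genes are not independent replicates. At stage 7, 2261 genes were higher in both knockdowns and 2151 lower in both, against 1028 and 843 for independent lists, a value that leaves out the shared controls, and 586 were opposite, against 1864. At stage 8 there were 2846, 2575 and 512, against 1182, 1005 and 2180. OTX1 MO and double MO had correlations of 0.94 and 0.96 at stages 7 and 8, against 0.48 and 0.63 simulated, and covariances of 0.748 and 1.12 against 0.0245 and 0.0405, with 13 and 9 genes opposite. With 2 WT libraries per stage a split would leave 1 library on each side, so the controls were not split, and part of the excess may come from the shared controls.

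Zygotic and maternal lists were set by RNA level in these WT libraries, so their direction against them is not independent evidence. The zygotic list of stage 9 held 1820 genes, including 32 of the 37 early mesendoderm genes. In E2F1 MO embryos 485 of these were higher and 195 lower at stage 7 (468 and 179 adjusted over the list alone; adjusted p = 0.017; median 0.37, or 0.00 with bounds), a call lost with the list set at a log2 fold of 1 (unadjusted p = 0.0143) or CPM under 5 (0.0177), and 159 higher and 472 lower at stage 8 (142 and 435; adjusted p = 0.0013; median -0.49, or -0.23 with bounds). In OTX1 MO embryos there were 252 higher and 231 lower at stage 7 (203 and 195; adjusted p = 0.96) and 142 higher and 641 lower at stage 8 (129 and 616; adjusted p = 3.6e-06; median -0.88, or -0.54 with bounds). In double MO embryos there were 252 and 219 at stage 7 (207 and 187; adjusted p = 1.0) and 152 and 695 at stage 8 (148 and 675; adjusted p = 1.1e-06; median -1.07, or -0.65 with bounds). Rescue against E2F1 MO gave 77 higher and 572 lower at stage 7 (72 and 549; adjusted p = 1.1e-06) and 33 and 553 at stage 8 (29 and 521; adjusted p = 2.3e-10). Of the 1155 genes of the stage 8 list 394 were higher and 155 lower in E2F1 MO at stage 7 (394 and 155; adjusted p = 0.0032), and of the 725 genes of the stage 7 list 184 were higher and 142 lower at stage 8 (182 and 142; adjusted p = 0.96). Of 435 maternal genes 77 were higher and 243 lower in E2F1 MO at stage 7 (80 and 250; adjusted p = 9.6e-11), and 198 and 77 at stage 8 (200 and 81; adjusted p = 2.4e-04, and adjusted p = 0.31 with an estimated correlation). Rescue against E2F1 MO gave 270 higher and 53 lower at stage 7 (282 and 56; adjusted p = 6.2e-18) and 254 and 23 at stage 8 (264 and 28; adjusted p = 1.2e-17).

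Stress and immune lists were measured beside these. In E2F1 MO at stage 7, 6 of 31 innate immune genes rose and 13 fell (6 and 15 adjusted over the list alone; adjusted p = 0.066). Of 31 p53 response genes 9 rose and 14 fell (10 and 14; adjusted p = 0.38), and of 30 heat-shock and immediate early genes 12 rose and 7 fell (12 and 7; adjusted p = 0.41). Of 40 oocyte and germ plasm genes 17 rose and 7 fell (17 and 8; adjusted p = 0.45), and of 14 replication-dependent histone genes 3 rose and 2 fell (3 and 2; adjusted p = 0.96). Only 2 adult blood, liver and ovarian follicle genes were measured, of which 1 rose and 0 fell (1 and 0; adjusted p = 0.48). Other comparisons of the knockdowns gave calls for these lists. In double MO against OTX1 MO at stage 7 the histone list was called higher (adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation), although edgeR called 0 of its 14 genes (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05 and 0 by DESeq2. This call was lost without OTX1 MO replicate 1 (unadjusted p = 0.038) or double MO replicate 2 (0.089), and with total counts alone (0.025). At stage 8 the p53 list was called lower there, with 1 risen and 3 fallen (1 and 4 adjusted over the list alone; adjusted p = 0.040, and adjusted p = 0.058 with an estimated correlation). That call was lost without OTX1 MO replicate 2 (unadjusted p = 0.11) or double MO replicate 1 (0.054), and with total counts alone (0.016). The interaction at stage 7 was positive for 13 innate immune genes and negative for 5 (14 and 6 adjusted over the list alone; adjusted p = 0.042, and adjusted p = 0.17 with an estimated correlation). It was not called without E2F1 MO replicate 1 (unadjusted p = 0.014), OTX1 MO replicate 2 (0.017) or double MO replicate 2 (0.027), nor with total counts alone (0.015). The rescue effect on oocyte and germ plasm genes differed between stages 8 and 7, positive for 13 and negative for 3 (15 and 3 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.38 with an estimated correlation).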

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

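The tests of explanations in this part were chosen only after the results they bear on were seen, while the tests of effect between stages were planned.

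The effect of an injection differed between stages in many genes, by a contrast of the 2 effects in edgeR. The E2F1 MO effect differed between stages 8 and 7 in 6269 genes and between stages 7 and 6 in 4739. The OTX1 MO, double MO and E2F1 rescue effects differed between stages 8 and 7 in 5110, 5155 and 4023 genes.

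E2F1 MO and WT embryos differed in 7589 and 8004 genes at stages 7 and 8, but in 313 to 1213 at stages 3 to 6. Timing cannot be judged by the 37.1% of E2F1 MO calls at stage 7 beyond each of WT stages 6 to 9. WT stage 7 itself lay 0.707 off the path of other WT stages (below), against 0.817 for E2F1 MO. An E2F1 morpholino effect as large beside the OTX1 morpholino is argued against as the whole cause. In the direction of their change, genes called in E2F1 MO at stage 7 had a median of 0.61 there. It was 0.00 in double MO against OTX1 MO (25th to 75th percentile -0.13 to 0.13), with no shared library. Other parents or clutches may contribute. At WT stage 7, 3 RNAs of stages 6 and 8 were missing (nostrin, slc6a14.1 and a locus without a symbol). WT stages 4, 5, 6, 8 and 9 each had 0 such gaps. Of RNAs at 10 CPM or more at WT stage 3, WT stage 7 lacked 2 present in E2F1 MO and 5 in rescue. At stage 6 both were 0. Few RNAs and no clutch labels leave clutch and injection inseparable, and an effect of E2F1 with OTX1 open.

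A set of 128 higher and 48 lower genes was called in the same direction in E2F1 MO at stages 3, 4 and 5, and of these 103 and 39 were called so at stage 6, 82 and 31 at stage 7 (9 and 7 in the opposite direction) and 84 and 26 at stage 8 (5 and 12 opposite). A loss of E2f1 that the added mRNA makes good is argued against, since the median change in rescue at stage 6 was 1.11 times that in E2F1 MO for the higher genes and 1.23 times for the lower. For the lower genes injection as such stays open. Their median at stage 8 was 0.12 in OTX1 MO (25th percentile -0.16), but only -0.21 in E2F1 MO itself. A clutch difference of stages 3 to 6 is argued against by double MO against OTX1 MO at stage 8. Their median of -0.29 could not decide, but 28 were called lower (counted after that), against 0.681 by chance. For the higher genes neither was excluded: their median in OTX1 MO at stage 8 was 0.195 (75th percentile 0.58) with 65 called higher, and in double MO against OTX1 MO it was 0.044, although 19 were called higher there against 1.62 by chance. An untested action of the E2F1 morpholino on RNAs other than e2f1 may account for the lower genes, with the injected amount left open. For the higher genes this action, injection and clutch cannot be told apart.

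Early mesendoderm and organizer genes were detected in E2F1 MO embryos at stage 7. Embryos merely further along WT activation would hold these genes near WT stage 8 levels. Of the 37, 21 could be judged (1 CPM or more there), and 15 of those were within 2-fold. This goes with timing, but timing and a direct effect cannot be told apart. That the E2F1 morpholino raises these genes by as large a factor beside the OTX1 morpholino is argued against by the interaction at stage 7, negative for 18 and positive for 0 of the 37 (camera adjusted p = 2.0e-04), and a smaller rise is left open by double MO against OTX1 MO at that stage (adjusted p = 0.55). A candidate explanation is that the rise needs OTX1, which no test here separates from a difference between clutches.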

How the results depend on the processing

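The comparison with each of WT stages 6 to 9, the list without e2f1 and the depth to which named genes are given were chosen only after the results were seen, and the other tests here were planned. Of 400 values of the 36 counts of called genes under the alternatives, 344 stayed within 1.5 times and 56 did not. The cause was not tested where none is given.

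E2F1 MO against WT gave 1950 calls at stage 4 and 787 at stage 5 with fewer libraries in the fit, and 861 at stage 4 and 495 at stage 6 with DESeq2. Rescue against E2F1 MO at stage 6 gave 56 with total counts alone, 169 with no filter, 5 with fewer libraries and 91 with DESeq2. Double MO against OTX1 MO at stage 7 gave 991 with no filter and 1392 with fewer libraries. Beyond each of WT stages 6 to 9, by construction fewer genes passed: 2818 and 2349 in E2F1 MO at stages 7 and 8, 701 and 1415 in rescue, 3152 and 3625 in OTX1 MO, and 3239 and 3687 in double MO.

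Leaving out 1 library at a time gave 519 to 793 calls for WT stage 4 against 3, 2919 to 3486 for stage 5 against 4 and 700 to 1010 for stage 6 against 5. For E2F1 MO against WT it gave 263 to 1256, 198 to 369, 257 to 291 and 159 to 211 at stages 3 to 6. Rescue against E2F1 MO gave 1 to 18 at stage 6 and 4121 to 6663 at stage 8, and rescue against WT 239 to 341 at stage 6. Double MO against OTX1 MO gave 172 to 1264 and 216 to 284 at stages 7 and 8. Of 926 pairs of a gene and a comparison that the rule names, 761 kept the call without any 1 library and 165 lost it. Of the 228 such pairs within the printed depth, 203 kept it and 25 lost it. At stages 3 to 6 of E2F1 MO the losses were 24 of 47, 20 of 41, 15 of 40 and 11 of 37.

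The zygotic list of stage 9 had an unadjusted p of 0.0143 in E2F1 MO at stage 7 with a fold of 1 and of 0.0177 with a limit of CPM under 5, where the call was lost. In OTX1 MO at stage 7 its p was 0.965 with total counts alone, and in double MO 0.778 with total counts alone, 0.960 with CPM under 0.5 and 0.850 without double MO replicate 2, with the opposite sign in these 4, and 0.710 to 0.994 without 1 of the other libraries. Of 117 list results 51 lost the call or turned direction with an estimated correlation, 4 with RLE factors and 10 with total counts alone, as did 40 of 492 values without 1 library. The covariance of the single knockdowns was 0.254 and 0.373 at stages 7 and 8 over genes of at least 5 CPM. With genes called at an adjusted p under 0.01, the rescue medians were 0.34 and -0.56 at stage 7 and 0.45 and -0.27 at stage 8 for genes of stage 6, 0.18 and -0.091 at stage 8 for genes of stage 7, and 0.076 at stage 7 for higher genes of stage 8. The log2 change of e2f1 in WT against stage 3, -0.40 at stage 7 and -0.41 at stage 8, turned to 0.10 and 0.12 with total counts alone.

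Total counts alone raised the share of higher calls from 51.4 to 66.8% in WT stage 7 against 6 and from 51.0, 53.1, 54.0 and 55.8% to 77.0, 72.6, 72.8 and 73.0% in stages 6, 7, 8 and 9 against 3, and lowered it from 51.7 to 39.6% in stage 10 against 9. With that scaling pkmyt1, zp4.2, fbn3, rpl15, rcc2 and stim1 lost their calls (adjusted p of 0.056, 0.064, 0.056, 0.087, 0.082 and 0.059). Replicate numbers are shared between groups, but they did not pair the libraries: over 231 pairs of groups the correlation of deviations ran from -0.25 to 0.46 with a median of 0.0013, and 12 were above 0.1. With the replicate number as a block, rescue against E2F1 MO at stage 6 gave 12 calls, and no other count moved by over 1.5 times and no list call changed. Among the genes given here fbn3, rcc2 and otx1 (adjusted p of 0.052, 0.050 and 0.053), and with a block within each stage rcc2 (0.10), lost a call. No alternatives were run for the differences of effects between stages, nor for list tests between WT stages beyond the estimated correlation. Depth limits statements on rare RNAs, as 3 counts correspond to 0.0706 to 0.329 CPM.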

Other observations

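The values in this part come from tests and sums chosen only after the results were seen, except the list tests, which were planned.

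Embryos were placed on the path of WT stages by their nearest point in log2 values. E2F1 MO embryos of stages 7 and 8 both fell at 7.44, rescue embryos at 6.22 and 6.25, OTX1 MO embryos at 6.64 and 7.39 and double MO embryos at 6.64 and 7.33. WT stage 7 and stage 8, placed without their own stage, fell at 6.74 and 8.23, at distances of 0.707 and 0.574 (root mean square, log2) from the path. The remaining distance from the path was 0.448 and 0.490 for rescue and 0.768 to 0.870 for the other injected groups of these stages, against 0.319 to 0.340 for E2F1 MO at stages 3 to 6.

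Neil3 RNA stood at 73.3 and 80.9 CPM in E2F1 MO and at 98.7 in rescue at both stages 7 and 8, and was at 0 in OTX1 MO and double MO. Nostrin was at 36.4 and 39.0 CPM in rescue, at 38.1 in WT stage 8, and below 0.1 in E2F1 MO, OTX1 MO and double MO at both stages. Lad1 was found at 6.70 and 12.3 CPM in WT at stages 7 and 8 and at 0.0687 or less in all injected groups.

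Lowered genes of the cleavage-stage set stayed low where the E2F1 morpholino was combined with that of OTX1. RNA of tmem203 stood at 7.17 and 5.69 CPM in double MO at stages 7 and 8, at 19.1 and 17.6 in OTX1 MO and at 14.2 and 12.8 in WT. Of the 48 genes 41 had a lower level in double MO than in OTX1 MO at each stage, and 30 and 28 were called lower with 0 called higher.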
